A study of Danio rerio with 27 samples.

How the data were processed

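Whole-brain RNA from 27 sibling zebrafish aged 3 months was sequenced after polyA selection with stranded libraries, all in batch 1 and with 13 cycles of amplification per the labels. The deposited table holds raw counts of read pairs per gene, with 1 column per library and 32520 genes, and the values were whole numbers. Per the submitters' processing notes, reads were trimmed with fastp 0.23.4, aligned with STAR 2.7.11b to GRCz11 and counted with featureCounts 2.0.6. Per the file headers, counting was forward stranded (strand option 1) on read pairs, with an overlap fraction of 1 and a minimum overlap of 35 bases, and without reads that mapped to several places or genes. The annotation release is not given in the sources used here. Total counts ran from 25374340 to 68093351 per sample. The floor covers counting error only, since reads without molecular identifiers are not independent molecules. The labels number replicates 1 to 3 within each genotype combination and describe the samples as separate brains, and they do not say whether any were handled together.

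Samples were grouped by the genotypes in the labels, with 3 samples in each of 9 combinations. Replicate numbers do not pair the samples: deviations of libraries with the same number in different groups correlated at a mean of 0.00814 across genes, and 11 of 27 libraries had their closest match under their own number. Gene symbols came from a table of zebrafish gene names matched by Ensembl ID, which gave a symbol to 29201 of 32520 IDs (89.8%) and left 3319 without one. That table writes 11996 symbols in capitals, as for human genes, and symbols are printed as it gives them.

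Genes were kept by the filterByExpr rule over the 9 combinations, which left 20756. Counts were scaled by the TMM method in edgeR 4.0.16 (R 4.3.3), and each gene was tested with edgeR's quasi-likelihood test in an additive model of psen1 genotype and chromosome 14 genotype, with 22 residual degrees of freedom. A gene was called at a Benjamini-Hochberg false discovery rate under 0.05 over all tested genes. A model of the 9 group means gave the interaction test and the comparisons within a single background. The test for TU/PK off the midpoint compared TU/PK with the mean of the homozygotes on the log scale. Levels are CPM on TMM-scaled library sizes, with the SD over samples, and fold changes come from the model.

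Called genes on each of the 25 chromosomes were compared with those on all others by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the chromosomes and 0.5 added to each cell for the odds ratio. The 20508 tested genes on these chromosomes were the background. The same test set genes within 5 Mb of psen1 against the rest of chromosome 17. These comparisons treat genes as independent, which neighbouring genes are not, so their p-values can be too small. The position of TU/PK between the homozygotes has an interval from 2000 bootstrap draws of the samples, which covers the spread between samples. Shares of genes higher or lower carry an exact (Clopper-Pearson) interval, which treats genes as independent. A fold against a group with no counts uses a floor of 3 counts over the group.

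The 36 gene lists of pathways, brain cell types and other tissues were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. The lists use zebrafish symbols. A symbol absent from the name table was matched to the capital symbol without its duplicate suffix, and all IDs under that symbol were taken, a rule made after the name table was seen and before any list was tested.

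Named genes followed a rule set before the data were examined. For each main comparison these were psen1, up to 8 genes of largest increase and 8 of largest decrease among called genes with a mean of at least 1 CPM, the same direction in all 3 backgrounds and a symbol that is not a clone name, and the 4 genes of smallest p whatever their symbol. The comparisons, tests, lists, distances and alternatives were also fixed before the data were examined. The alternatives were median-ratio size factors, library size alone, no filter, a filter at 1 CPM in 9 samples, DESeq2 1.42.0, limma-voom with quality weights, group means, only the samples compared, the replicate number as a block, surrogate variables from sva 3.50.0, a false discovery rate of 0.01, other distances, 1 gene per 100 kb and leaving out each library. Leaving out both libraries that stood apart, leaving out psen1 and counting bins of 100 kb in place of genes were added after seeing the data. Base changes, allele-specific expression and splicing were left out because gene counts do not hold them.

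The main test was tested on simulated data in which 50 genes of each size were changed. At 9 samples against 9 it recovered 8% of genes changed 1.25-fold, 50% at 1.5-fold, 70% at 2-fold and 78% at 4-fold for PK/PK against TU/TU, and 10%, 42%, 70% and 90% for T428del/+ against +/+. At 3 against 3 within TU/TU it recovered 0%, 4%, 42% and 74%. False calls made up 5.5%, 2.75% and 3.23% of the calls. These simulations drew each gene independently and held no library that stood apart. In the real data 543 genes for PK/PK against TU/TU and 657 for T428del/+ had an unadjusted p under 0.05, against 1038 by chance alone. Recovery and false calls in the real data may therefore differ.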

Results

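RNA sequencing measured gene expression in whole brains of sibling zebrafish aged 3 months. The 27 samples were grouped by genotype at a pair of loci, with 3 samples in each of the 9 combinations. On chromosome 17 the fish carried wild-type psen1 (+/+), a single copy of T428del, which models early-onset familial Alzheimer's disease, or a single copy of W233fs, which models familial acne inversa. On chromosome 14 they carried alleles of the TU strain, the PK strain or a copy of each. Every genotype at a locus was therefore present in 9 samples. Total counts per sample ran from 25374340 to 68093351 read pairs, with a median of 34374741.

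The psen1 transcript, which encodes the catalytic subunit of gamma-secretase, was measured first in every sample. It stood at 44.2 ± 4.56 CPM (counts scaled to the library total; mean ± SD, n = 9) in +/+ brains, at 47.5 (range 40 to 66.7, n = 9) in T428del/+ brains and at 23.7 ± 2.04 (n = 9) in W233fs/+ brains. The highest W233fs/+ sample, at 27.7 CPM, lay below the lowest +/+ sample, at 39.1 CPM, so the transcript level separated all 9 W233fs/+ samples from the other genotypes. The psen1 gene (ENSDARG00000004870) lies on chromosome 17 from 51206225 to 51224800 in GRCz11. Gene counts cannot show the base changes themselves, so the level of this transcript does not tell T428del/+ from +/+ samples.

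**Figure D1:**
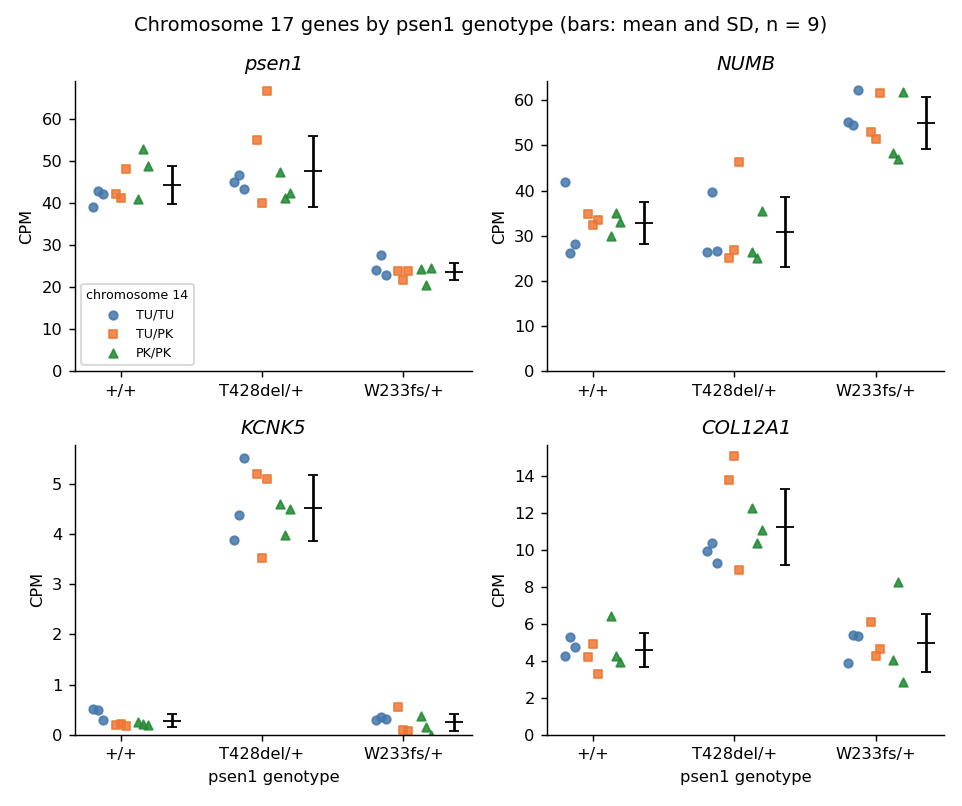
Expression in CPM of psen1, NUMB, KCNK5 and COL12A1 by psen1 genotype, with 1 point per sample, colours and shapes for the chromosome 14 genotype, and bars for the mean and SD (n = 9). W233fs/+ samples sit between 20.4 and 27.7 CPM for psen1 and between 47 and 62.3 CPM for NUMB, and T428del/+ samples sit between 3.51 and 5.5 CPM for KCNK5.

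The comparison of W233fs/+ with +/+ brains asked which genes differ with the frameshift allele. Expression of psen1 fell by 0.9 on the log2 scale (SE 0.09), to 0.536 of the wild-type level, and it was lower in each chromosome 14 genotype. NUMB, which encodes an adaptor protein that antagonises Notch signalling, was 1.68-fold higher, at 55 ± 5.77 CPM (n = 9) against 32.8 ± 4.59 (n = 9), and the ranges of the samples did not overlap. NUMB (ENSDARG00000027279) lies 0.62 Mb from psen1, from 51821906 to 51893123. These were the 2 genes called among 20756 tested, with adjusted p = 1.38e-06 for psen1 and 0.00473 for NUMB (edgeR quasi-likelihood test, Benjamini-Hochberg), and both lie on chromosome 17. In the same comparison, 573 genes had an unadjusted p under 0.05, against 1038 by chance alone. The uncalled genes next by p were si:ch73-174h16.5 on chromosome 7 and PDZD7 on chromosome 13, with log2 fold changes of 0.65 (SE 0.19) and 0.98 (SE 0.28) and an adjusted p of 1 for each (edgeR quasi-likelihood test, Benjamini-Hochberg).

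The comparison of T428del/+ with +/+ brains asked the same of the Alzheimer's disease allele. KCNK5, which encodes a background potassium channel, was 16.6-fold higher in T428del/+ brains, at 4.51 ± 0.662 CPM (n = 9) against 0.283 ± 0.128 (n = 9). COL12A1, which encodes a fibril-associated collagen chain, was 2.45-fold higher, at 11.3 ± 2.1 against 4.59 ± 0.906 CPM (n = 9 each). The unnamed locus si:ch211-235i11.5 was 1.85-fold higher, at 8.96 ± 1.39 against 4.83 ± 0.865 CPM (n = 9 each). For these 3 genes no T428del/+ sample overlapped the +/+ samples. CLIC4, which encodes a chloride intracellular channel protein, was lower, at 34.7 ± 7.97 against 53.7 ± 8.76 CPM (n = 9 each). The psen1 transcript itself differed by a log2 fold change of 0.10 (SE 0.09), which did not pass the test (adjusted p = 1, edgeR quasi-likelihood test, Benjamini-Hochberg).

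These 4 genes were all that the test called for T428del/+, 3 higher and 1 lower, and all lie on chromosome 17. KCNK5 (ENSDARG00000023587, from 48683769), COL12A1 (ENSDARG00000078322, from 49785495) and si:ch211-235i11.5 (ENSDARG00000093378, from 50413084) start 2.52, 1.42 and 0.79 Mb from psen1, and CLIC4 (ENSDARG00000022995, from 25444323) starts 25.76 Mb away. Adjusted p was 2.35e-07, 0.000149, 0.000323 and 0.0408 in that order (edgeR quasi-likelihood test, Benjamini-Hochberg). The CLIC4 call was lost in 14 of the 27 fits that each left out a sample, with adjusted p up to 0.15, and with group means, only the samples compared, the replicate block or surrogate variables, up to 0.191 (edgeR quasi-likelihood test, Benjamini-Hochberg). The count rose from 4 to 7 without +/+ TU/PK replicate 1 and to 8 without T428del/+ TU/PK replicate 3.

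Set directly against each other, W233fs/+ and T428del/+ brains differed in 10 genes, 2 higher and 8 lower in W233fs/+, and all 10 lie on chromosome 17. Compared with T428del/+, W233fs/+ brains had lower psen1 (log2 fold change -1, SE 0.09), KCNK5 (-4.20, SE 0.37) and COL12A1 (-1.17, SE 0.16), and higher NUMB (0.83, SE 0.11) and CLIC4 (0.68, SE 0.11). QPCT, the glutaminyl cyclase that forms pyroglutamate at protein N-termini, was lower at 14.6 ± 2.04 against 27.1 ± 6.1 CPM (n = 9 each). The acylphosphatase gene acyp1 was lower at 22.6 ± 4.39 against 38.2 ± 5.57 CPM (n = 9 each), and FCF1, a factor of ribosomal RNA processing, at 17.6 ± 2.21 against 25 ± 3.72 CPM (n = 9 each). In +/+ brains QPCT stood at 17 ± 6.34 CPM (n = 9), nearer to the W233fs/+ level. There acyp1 and FCF1 stood at 29.6 ± 6.89 and 21.9 ± 3.46 CPM (n = 9 each), between the mutants. QPCT, acyp1 and FCF1 were not called in either mutant against +/+, so their direction here is relative to T428del/+ only. QPCT, acyp1 and FCF1 start 8.36, 0.96 and 1.75 Mb from psen1. The other called genes, si:ch211-235i11.5 (log2 fold change -0.86) and ENSDARG00000103849 (-1.18), were outside the rule for named genes and were chosen after their values were seen. Adjusted p for the 10 genes ran from 6.86e-08 for psen1 and KCNK5 to 0.0279 for FCF1 (edgeR quasi-likelihood test, Benjamini-Hochberg). The FCF1 call was lost in 10 of the 27 fits that each left out a sample, with adjusted p up to 0.0941, and was also lost with only the samples compared (0.128) and without both libraries that stood apart (0.121; edgeR quasi-likelihood test, Benjamini-Hochberg), as it was by limma-voom (0.0538). QPCT was not called with library size alone (adjusted p = 0.0798), nor CLIC4 with only the samples compared (0.0669; edgeR quasi-likelihood test, Benjamini-Hochberg).

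No gene was called in both mutants against +/+. The count of shared calls by edgeR was 0, while 82 genes had an unadjusted p under 0.05 in both with the same direction. Both comparisons use the same 9 control samples. Simulated libraries with no change, with both groups set against the same simulated controls, gave a mean of 202 such genes, and independent lists would give 9.02. Across genes, which are not independent replicates, the fold changes of the 2 mutants correlated at r = 0.447, where the simulations gave a mean of 0.499 (SD 0.0123). The covariance of 0.0562 was 0.063 in the simulations. The simulations drew each gene independently and held no library that stood apart. The real comparisons had 657 and 573 genes at an unadjusted p under 0.05, against 1038 by chance alone. Values below the simulated ones therefore do not show that the mutants are less alike than chance. With the controls split so that each mutant had its own, r averaged 0.0277.

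The comparison of PK/PK with TU/TU brains asked which genes differ with the strain of origin of chromosome 14. ENSDARG00000100547 was near absent in PK/PK brains, at 0.084 ± 0.101 CPM (n = 9), against 4.28 ± 0.787 (n = 9) in TU/TU brains, a log2 fold change of -5.61 (SE 0.36). Its neighbour ENSDARG00000104112 had no count in any PK/PK sample and 0.752 ± 0.27 CPM (n = 9) in TU/TU, which makes it at least 85.1-fold lower against a floor of 3 counts over the group. The Nudix hydrolase gene nudt22 was 2.13-fold higher in PK/PK, at 5.92 ± 0.874 against 2.78 ± 0.789 CPM (n = 9 each). The metalloprotease gene adam19b fell by 0.83 on the log2 scale (SE 0.12), from 26.4 ± 6.06 to 14.8 ± 1.04 CPM (n = 9 each), and cab39l1, a relative of the MO25 scaffold of the LKB1 kinase, fell by 0.59 (SE 0.10), from 24.9 ± 3.33 to 16.6 ± 2.58 CPM (n = 9 each).

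The test called 9 genes for PK/PK against TU/TU, 3 higher and 6 lower, and all 9 lie on chromosome 14. They start between 6546516, at adam19b, and 35464994, at si:ch211-203d1.3, and the pair near absent in PK/PK starts at 11317070 and 11338375. The remaining called genes were si:ch211-127l15.7 (log2 fold change 1.63, SE 0.23) and si:ch211-203d1.3 (-1.17, SE 0.15), with zgc:113364 (0.641 ± 0.298 against 0.00647 ± 0.0194 CPM, n = 9 each) and si:dkeyp-44a8.2 (-0.61, SE 0.10) chosen after their values were seen. Adjusted p ran from 6.61e-11 for ENSDARG00000100547 to 0.0159 for nudt22 (edgeR quasi-likelihood test, Benjamini-Hochberg). Without W233fs/+ TU/TU replicate 1, nudt22 was no longer called, with an adjusted p of 0.0611 (edgeR quasi-likelihood test, Benjamini-Hochberg).

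**Figure D2:**
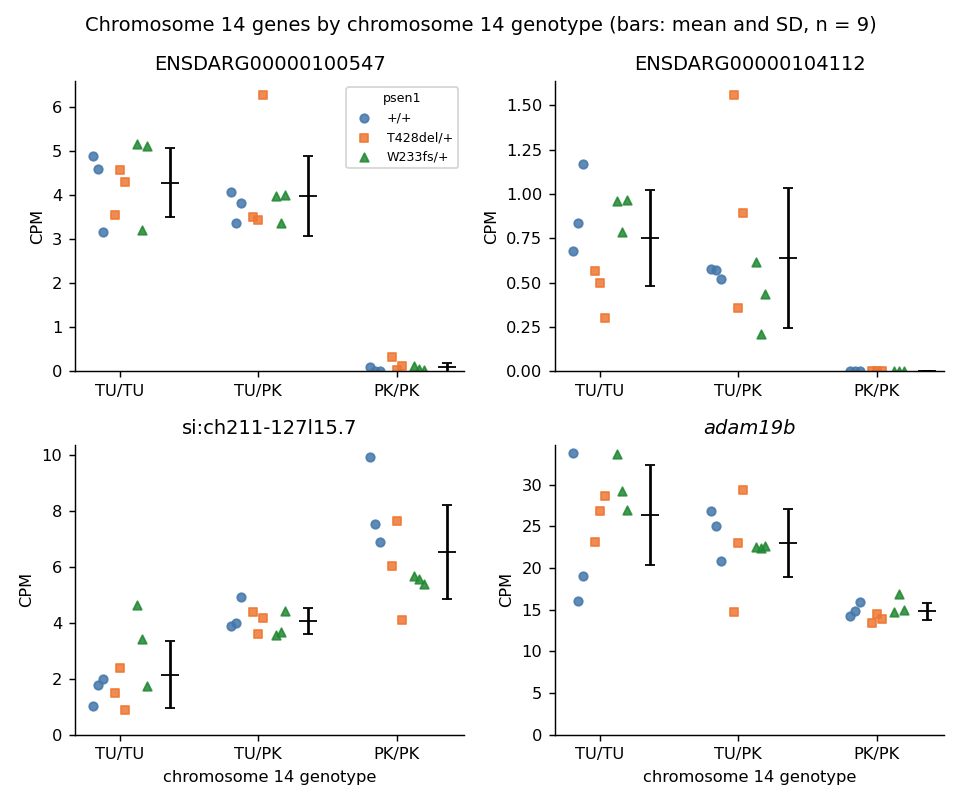
Expression in CPM of ENSDARG00000100547, ENSDARG00000104112, si:ch211-127l15.7 and adam19b by chromosome 14 genotype, with 1 point per sample, colours and shapes for the psen1 genotype, and bars for the mean and SD (n = 9). For ENSDARG00000100547 the PK/PK samples sit at or below 0.326 CPM and the TU/PK samples between 3.37 and 6.28 CPM.

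In brains with a copy of each chromosome 14 allele the mean lay between those of the homozygotes for all 9 of these genes. The genes were chosen by the gap between the homozygotes in the same samples, which favours such a mean, so this count is no test of it. The position of the TU/PK mean, measured in CPM from TU/TU (0%) to PK/PK (100%), had a median of 32.1%, from 7.19% for ENSDARG00000100547 to 73% for si:dkeyp-44a8.2. The position of ENSDARG00000100547 (95% bootstrap interval -12.6% to 21.3%) lay close to TU/TU, and that of ENSDARG00000104112 was 15.3% (-31.2% to 45.5%). The interval also reached past a homozygote for nudt22 (-5.55% to 44.5%), adam19b (-15.5% to 56%) and si:dkeyp-44a8.2 (33.5% to 102%), so for these 5 genes a level between the homozygotes is not shown with all libraries. On the log scale TU/PK lay off the midpoint of the homozygotes for these 2 genes (adjusted p = 2.96e-07 and 0.000887, edgeR quasi-likelihood test, Benjamini-Hochberg), but with PK/PK at or near 0 a TU/PK level halfway in CPM would also lie off it, so that test says nothing about the position. Without T428del/+ TU/PK replicates 1 and 3, which stood apart from the other libraries, the positions of ENSDARG00000100547 and ENSDARG00000104112 were 13.4% (1.07% to 23.3%) and 37.6% (13.6% to 53.7%), the latter farther from TU/TU than nudt22 (17.9%), adam19b (26.7%), zgc:113364 (28.4%) and cab39l1 (31.4%). That of si:dkeyp-44a8.2 was then 87.1% (75.9% to 99%), with the interval inside the homozygotes. The intervals of nudt22 (-11.8% to 51.4%) and adam19b (-12.3% to 46.7%) still reached past TU/TU. ENSDARG00000100547 and ENSDARG00000104112 belong to a run of 6 genes on the same strand between RLIM and GLOD5, whose summed level was 7.53 CPM in TU/TU, 7.29 in TU/PK and 2.17 in PK/PK.

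Between PK/PK and TU/PK brains the same pair of genes, ENSDARG00000100547 and ENSDARG00000104112, was called, both lower in PK/PK (adjusted p = 1.01e-10 and 7.61e-06, edgeR quasi-likelihood test, Benjamini-Hochberg). LMAN2, a lectin of the early secretory pathway, was at 61.7 ± 4.19 against 43.8 ± 8.07 CPM (n = 9 each) and adam19b at 14.8 ± 1.04 against 23 ± 4.08 CPM (n = 9 each), and neither passed, with an adjusted p of 0.0861 for each (edgeR quasi-likelihood test, Benjamini-Hochberg). Both passed by DESeq2 (adjusted p = 0.00252 for each) and limma-voom (0.0153 for each), LMAN2 also with group means (0.0146) and adam19b with only the samples compared (0.0482; edgeR quasi-likelihood test, Benjamini-Hochberg). LMAN2 passed without W233fs/+ TU/PK replicate 1 (adjusted p = 8.19e-05) and adam19b passed without T428del/+ TU/PK replicate 1 (0.00702) or without +/+ TU/TU replicate 2 (0.0199; edgeR quasi-likelihood test, Benjamini-Hochberg). The count rose from 2 to 5 without T428del/+ TU/PK replicate 1.

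Between TU/PK and TU/TU brains edgeR called 0 genes, with 458 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom each called 1. The count in edgeR was also 1 with surrogate variables and 1 without both libraries that stood apart. The genes of smallest p were zgc:113364 (0.225 ± 0.281 against 0.00647 ± 0.0194 CPM, n = 9 each), SNRNP25 on chromosome 3 (7.44 ± 2.34 against 11.7 ± 3.05 CPM, n = 9 each), si:ch211-127l15.7 (4.07 ± 0.452 against 2.15 ± 1.2 CPM, n = 9 each) and si:dkeyp-44a8.2 (127 ± 32.6 against 170 ± 13.1 CPM, n = 9 each). The last of these passed without T428del/+ TU/PK replicate 3, where its log2 fold change was -0.56 and its adjusted p 2.53e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg), and the count was then 1.

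The title of the series concerns selection of replicate groups by genotype, so the position of the differing genes was compared between chromosomes. In each main-effect comparison with a call, the odds of a gene being called were higher on the chromosome whose genotype was compared than on the other chromosomes. For chromosome 14 the odds ratio was 526 for PK/PK against TU/TU (adjusted p = 2e-12) and 137 for PK/PK against TU/PK (0.031), by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 25 chromosomes. The 137 rests on 2 neighbouring genes, and with bins of 100 kb in place of genes, chosen after seeing the data, both fell in 1 bin, which cannot pass after adjustment (86.4, adjusted p = 0.841), while for PK/PK against TU/TU 8 bins gave 501 (3.73e-11, Fisher's exact test). Keeping 1 gene per 100 kb left a single called gene for PK/PK against TU/TU, which cannot pass either (85.9, adjusted p = 0.845, Fisher's exact test). For chromosome 17 it was 226 for T428del/+ (adjusted p = 5.44e-05), 125 for W233fs/+ (0.037) and 531 for W233fs/+ against T428del/+ (1.68e-13), by the same Fisher's exact test. With psen1 itself left out, a choice made after seeing the data, a single called gene remained for W233fs/+, which cannot pass after adjustment (odds ratio 75.1, adjusted p = 0.961, Fisher's exact test), so that comparison has too few called genes to tell, and the last odds ratio was 481 (adjusted p = 4.37e-12, Fisher's exact test). Since the called genes were few, the 200 genes of smallest p were compared in the same way. Chromosome 14 held 90 of them for PK/PK against TU/TU (odds ratio 25.9), 21 for TU/PK against TU/TU (3.42) and 38 for PK/PK against TU/PK (7). Chromosome 17 held 49 for T428del/+ (8.75), 23 for W233fs/+ (3.41) and 59 for W233fs/+ against T428del/+ (11.4), and in all 6 comparisons the chromosome compared ranked 1 among the 25.

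Fisher's exact test treats genes as independent, which neighbouring genes are not, so its p-values here are too small. Random regroupings of the samples put up to 38 chromosome 17 genes among the 200 for T428del/+ and up to 31 for W233fs/+, with medians of 7 and 6. The largest adjusted p among these 6 comparisons was 0.000156, for TU/PK against TU/TU (Fisher's exact test, Benjamini-Hochberg), and that value rose to 0.0594 without +/+ TU/PK replicate 1 and to 0.0591 without W233fs/+ TU/TU replicate 3. For W233fs/+ it was 0.112 with surrogate variables (odds ratio 2.3) and 0.145 with 1 gene per 100 kb (3.39, Fisher's exact test), and 5 of 100 regroupings of the samples held as many, so that enrichment is not separated from chance. For PK/PK against TU/PK the odds ratio of called genes fell to 45.9 without +/+ PK/PK replicate 2 (adjusted p = 0.0902, Fisher's exact test) and rose to 304 without T428del/+ TU/PK replicate 1. That for T428del/+ rose to 382 without +/+ TU/PK replicate 1 and to 434 without T428del/+ TU/PK replicate 3. That for W233fs/+ against T428del/+ fell to 196 without +/+ PK/PK replicate 3 and to 214 without T428del/+ PK/PK replicate 2 or T428del/+ TU/TU replicate 3. Genes were called on other chromosomes under some alternatives. In edgeR these were 4 for T428del/+ and 2 for W233fs/+ against T428del/+ with surrogate variables, 1 each for PK/PK against TU/TU and W233fs/+ against T428del/+ with only the samples compared, and 1 for the latter with library size alone. Leaving out a library gave 1 such gene in 3 of the fits for W233fs/+ against T428del/+ and in 1 for PK/PK against TU/PK. DESeq2 called 2 such genes for PK/PK against TU/TU, 10 for PK/PK against TU/PK, 4 for T428del/+ and 4 for W233fs/+ against T428del/+, and limma-voom with quality weights called 1, 19, 0 and 2, where the main edgeR test called 0 in each with 543, 937, 657 and 1399 genes at an unadjusted p under 0.05 in the whole genome.

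**Figure D3:**
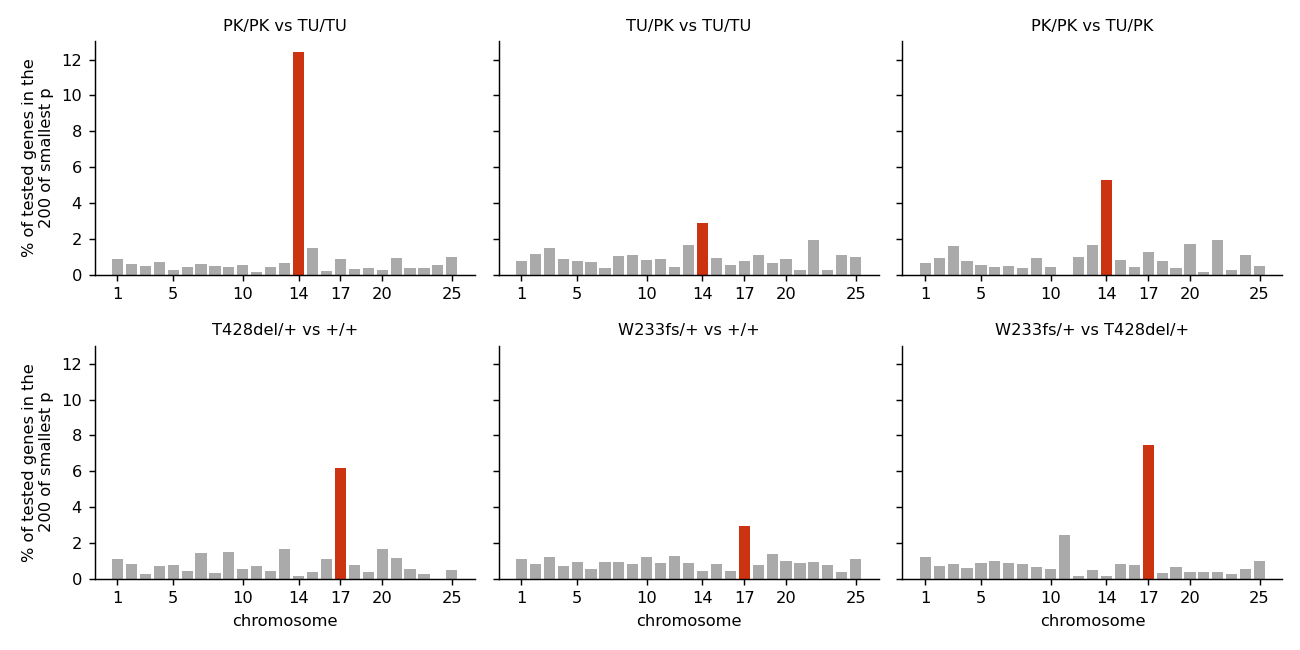
Percent of the tested genes of each chromosome that were among the 200 of smallest p, for the 6 main comparisons, with the chromosome whose genotype was compared in red. The red bar stands at 12.4% for PK/PK against TU/TU and at 2.9% for TU/PK against TU/TU, and it ranks 1 in each panel.

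Along chromosome 17 genes near psen1 were called more often for T428del/+ and for W233fs/+ against T428del/+. The Fisher p-values below treat neighbouring genes as independent, so they can be too small. Within 5 Mb of psen1, 3 of 98 tested genes were called for T428del/+, among them KCNK5, against 1 of 691 farther away (odds ratio 16.9, p = 0.00678, Fisher's exact test, two-sided). For W233fs/+ the 2 called genes, psen1 and NUMB, were both within 5 Mb (odds ratio 35.8, p = 0.0153, Fisher's exact test), but psen1 is by definition there, and without it a single gene was left, 1 of 97 against 0 of 691, too few to pass (p = 0.123, Fisher's exact test). For W233fs/+ against T428del/+, 7 of 98 were called within 5 Mb and 3 of 691 beyond (odds ratio 16.1, p = 3.27e-05, Fisher's exact test), and without psen1 6 of 97 (odds ratio 14, p = 0.000186, Fisher's exact test). With each library left out in turn the odds ratio for T428del/+ ran from 5.53 (p = 0.046, Fisher's exact test), without +/+ TU/PK replicate 1, to 50.6, without W233fs/+ TU/PK replicate 2. That for W233fs/+ against T428del/+ fell to 8.52, without +/+ PK/PK replicate 1 (p = 0.000366, Fisher's exact test), and to 10.2 without T428del/+ TU/TU replicate 3. Genes with an unadjusted p under 0.05 made up 19.4%, 18.4% and 30.6% of those within 5 Mb in these comparisons, and 9.84%, 3.04% and 14.2% of those beyond (17.5% within 5 Mb for W233fs/+ without psen1, p = 2.97e-07, Fisher's exact test). Along chromosome 14 the labels do not give the position of the marker genotyped, and called genes for PK/PK against TU/TU occurred in 6 of the 5 Mb windows.

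**Figure D4:**
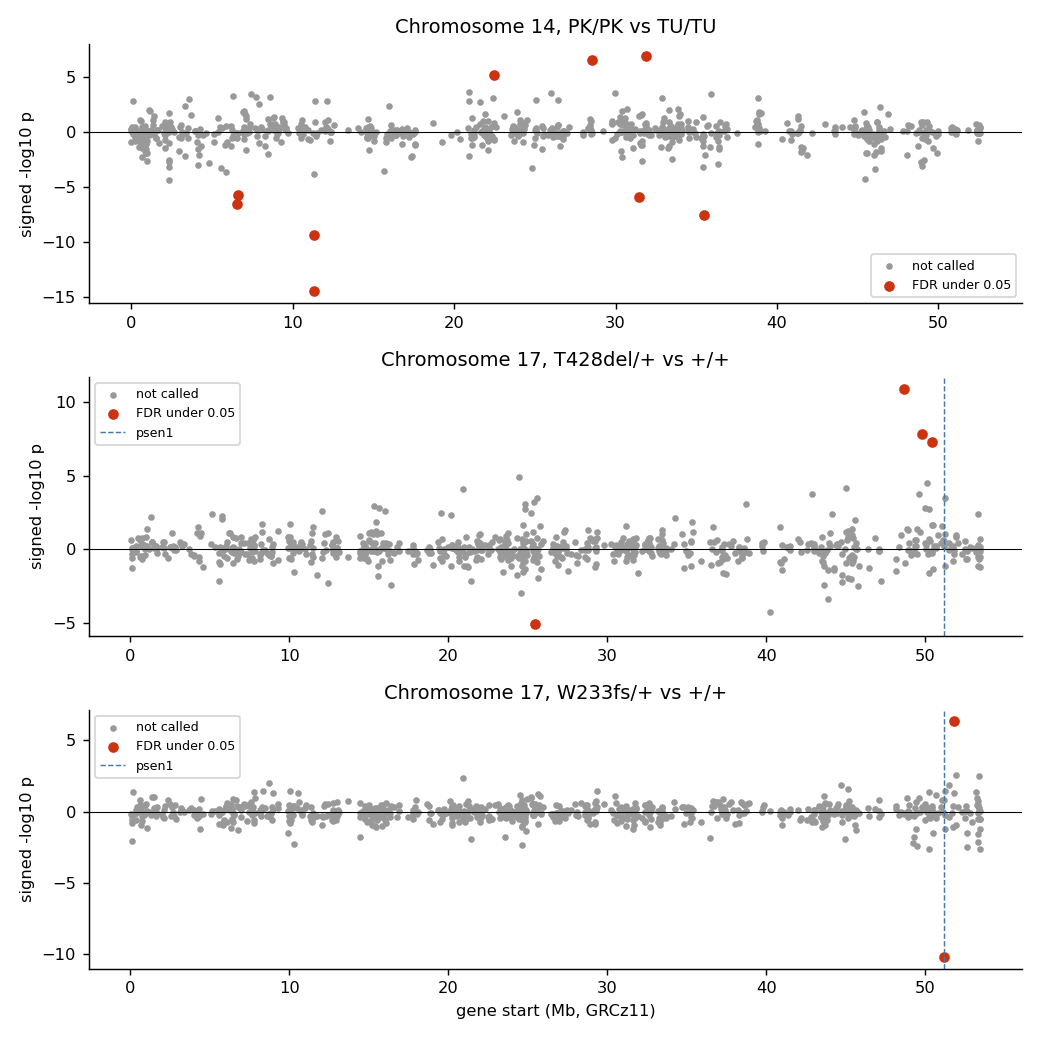
Signed -log10 p (unadjusted, positive for higher expression) against gene start in Mb along chromosome 14 for PK/PK against TU/TU, and along chromosome 17 for both psen1 alleles against +/+, with 1 point per tested gene and the position of psen1 as a dashed line. Red points are the 9, 4 and 2 genes past the false discovery rate of 0.05.

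On chromosome 14, genes differing between PK/PK and TU/TU went both ways: of 68 with an unadjusted p under 0.01, 28 were higher and 40 lower in PK/PK (58.8% lower, 95% interval 46.2% to 70.6%, exact binomial p = 0.182). On chromosome 17, 32 of 45 such genes were higher in T428del/+ than in +/+ brains (exact binomial p = 0.00661), but 52 of 87 with an unadjusted p under 0.05 were (p = 0.0857, exact binomial), and 14 of 17 under 0.001 (p = 0.0127, exact binomial). In W233fs/+ 5 of 15 under 0.01 were higher (p = 0.302, exact binomial), and against T428del/+ 43 of 60 were lower (p = 0.00107, exact binomial; 82 of 128 under 0.05 and 21 of 29 under 0.001). These genes are neighbours and not independent, so the binomial p-values are too small.

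Within a single background the comparisons set 3 samples against 3, with the spread pooled over the 9 groups. The psen1 transcript was called lower for W233fs/+ within TU/PK (log2 fold change -0.93, SE 0.14) and within PK/PK (-1.04, SE 0.14). KCNK5 was called higher for T428del/+ within TU/PK (4.57, SE 0.66) and within PK/PK (4.24, SE 0.66). ENSDARG00000100547 was called lower in PK/PK than in TU/TU in each psen1 genotype, by log2 fold changes of -6.88, -4.73 and -5.88 in +/+, T428del/+ and W233fs/+, but in T428del/+ it was the single call and was lost with only the samples compared. Within TU/PK, T428del/+ also differed from +/+ in 4 genes off chromosome 17, with CCK (0.86, SE 0.15) and SELENOK (1.14, SE 0.17) higher and TMEM121B (-1.23, SE 0.22) and RASA2 (-1.75, SE 0.32) lower, and 2 of those 3 T428del/+ samples stood apart from all other libraries. Within PK/PK, HEPACAM (1.36, SE 0.24), MYADM (1.41, SE 0.24) and ENSDARG00000109929 (2.85, SE 0.50) were called higher in T428del/+, with an adjusted p of 0.0498 for each (edgeR quasi-likelihood test, Benjamini-Hochberg). Their controls, the +/+ PK/PK samples, had the lowest scaling factors (0.94, 0.969 and 0.954) after the libraries that stood apart. These controls also lay highest on the first principal component after those libraries (35.3, 19.8 and 15.3). A shift of these controls is therefore not separated from an effect of T428del/+. The counts within these backgrounds were unstable. Without a library at a time those for T428del/+ differed in all 27 fits, running from 0 to 73 within PK/PK, where it had been 4, and from 0 to 4540 within TU/PK, where it had been 6. Within PK/PK it was 1 with median-ratio factors, library size alone, no filter or surrogate variables, 79 by DESeq2, 346 by limma-voom, 92 with only the samples compared and 291 without both libraries that stood apart. For W233fs/+ the count of 1, psen1, fell to 0 within TU/PK without any 1 of the 6 samples compared and at a false discovery rate of 0.01, and ran from 0, without W233fs/+ PK/PK replicate 2, to 13 within PK/PK. The genes named here were chosen after their values were seen.

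Within TU/TU, edgeR called 0 genes for T428del/+, where 505 had an unadjusted p under 0.05 and DESeq2 called 8 and limma-voom 2, and 0 for W233fs/+, where the numbers were 468, 12 and 2. The test of whether the psen1 effect depended on the chromosome 14 genotype called 0 genes in edgeR, with 425 called by DESeq2 and 72 by limma-voom. In edgeR 2487 genes had an unadjusted p under 0.05, more than the 1038 by chance alone, and the cause of this excess was not tested. Comparisons within a background exceeded 1038 only where they used T428del/+ TU/PK or +/+ PK/PK samples. These were T428del/+ within TU/PK (4261) and PK/PK (1988), W233fs/+ within PK/PK (1833) and PK/PK against TU/TU within +/+ (1445). The others had 272 to 505, so the excess need not be spread over all groups. The interaction test called 2600 genes without T428del/+ TU/PK replicate 2, when the libraries that stood apart were the only ones left in their group, and 1 without +/+ PK/PK replicate 3. The effects named above are therefore not shown to differ between backgrounds, and among the 19 genes called in the main comparisons the lowest interaction p, adjusted over these genes, was 0.277 (edgeR quasi-likelihood test, Benjamini-Hochberg).

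A pair of libraries, T428del/+ TU/PK replicates 1 and 3, stood apart from the rest. Mitochondrially encoded genes took 21.8% and 20.7% of their counts, 20139 and 20045 genes had a count, and their scaling factors were 0.85 and 0.843, with totals of 36.3 and 53 M read pairs. They also differed from each other: marker genes of erythrocytes were 0.94 above the median library in replicate 1 and 0.54 below it in replicate 3 on the log2 scale. Without both, a choice made after seeing the data, the counts were 15 for PK/PK against TU/TU, 1 for TU/PK against TU/TU, 17 for PK/PK against TU/PK, 12 for T428del/+, 2 for W233fs/+ and 15 for W233fs/+ against T428del/+. Of these, 1, 0, 6, 2, 0 and 1 lay on other chromosomes than the one compared.

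The gene lists fixed before the data were examined described pathways and cell types, and none passed a test with an estimated correlation. Genes of the interferon response had a median log2 fold change of 0.70 in T428del/+ brains, and 29 of 31 were higher. Their preset-correlation test gave an adjusted p of 4.1e-18 and an adjusted p = 0.27 with an estimated correlation. Members with the smallest p were stat2 (0.83, SE 0.30), SOCS1 (0.90, SE 0.33) and RSAD2 (0.70, SE 0.27), with 0 members called over all genes by edgeR, 8 at an unadjusted p under 0.05 and 0 adjusted over the list alone. All 3 T428del/+ TU/PK samples were among the 5 libraries with the highest mean of this list, at 1.89, 2.4 and 0.97 above the median library.

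Photoreceptor genes, which are expressed in the retina and the pineal organ, were lower in PK/PK than in TU/TU for 25 of 25 members, with a median log2 fold change of -1.17 (adjusted p = 3.6e-07 with the preset correlation, adjusted p = 0.99 with an estimated correlation). They were higher for 20 of 25 members in both W233fs/+ and T428del/+ brains (medians 1.12 and 0.75; adjusted p = 0.0017 and 0.03 preset, adjusted p = 0.69 and 0.73 with an estimated correlation). The 3 libraries with the most photoreceptor transcript stood 3.36, 3.02 and 2.32 above the median library, and they were T428del/+ TU/TU replicate 1, W233fs/+ TU/TU replicate 3 and W233fs/+ TU/PK replicate 1.

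Cytosolic ribosome genes had small shifts of opposite sign: 82 of 82 members were higher in T428del/+ brains (median 0.12), 80 of 82 lower in W233fs/+ brains (median -0.14) and 81 of 82 higher in PK/PK brains (median 0.09), with adjusted p of 2.9e-07, 9.7e-15 and 8.4e-07 preset and adjusted p = 0.73, 0.69 and 0.99 with an estimated correlation. Nuclear genes of oxidative phosphorylation had medians of 0.08, -0.12 and 0.07 in the same order (adjusted p = 0.00034, 3.6e-11 and 0.00076 preset, adjusted p = 0.73, 0.69 and 0.99 with an estimated correlation). Skeletal muscle and erythrocyte markers had medians of -0.67 and -0.27 in W233fs/+ brains (adjusted p = 0.00052 and 0.0017 preset, adjusted p = 0.69 for each with an estimated correlation). The gamma-secretase list was called lower for W233fs/+ (adjusted p = 0.006 preset, adjusted p = 0.69 with an estimated correlation), and without chromosome 17, which holds psen1, its adjusted p was 0.72. PSEN2, the other presenilin, had a log2 fold change of 0.05 in W233fs/+ brains, and Notch signalling genes had a median of -0.01 (adjusted p = 0.82 preset).

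With the preset correlation, 16 of the 36 lists were called for T428del/+ (11 higher, 5 lower), 10 for W233fs/+ (2 higher, 8 lower) and 5 for PK/PK against TU/TU (3 higher, 2 lower). Random regroupings of the same samples gave a median of 9 called lists, so these counts do not separate the genotypes from chance. Camera with an estimated correlation called 0 lists in each comparison, with 3, 1 and 0 at an unadjusted p under 0.05, and fry called 0, with 2, 1 and 0. Adjusted over the list alone, 4 lists held a called member for T428del/+, 1 for W233fs/+ and 0 by edgeR for PK/PK. The count for T428del/+ fell to 7 without T428del/+ TU/PK replicate 1, and that for PK/PK fell to 2 without +/+ PK/PK replicate 1 or 2 and to 3 without W233fs/+ PK/PK replicate 1, +/+ TU/TU replicate 3 or T428del/+ TU/TU replicate 2.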

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

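The tests of gene length, of cell markers, of the tandem cluster and of a silent PK copy were chosen after the result was seen, and the test without mitochondrial genes was set before. A sample counted as far from the others when its gap to the nearest exceeded 0.493 of the range of the 9 samples of its genotype. Of 80 groups checked, 12 held such a sample. Chance gives about 1 in 20 for independent values with a normal spread, but groups shared libraries and levels need not spread so. The 12 are therefore not shown to exceed chance.

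T428del/+ TU/PK replicate 3 had the highest total among T428del/+ samples, at 53 M read pairs against 37.6 M for the next. +/+ TU/TU replicate 2 had the highest total among TU/TU samples, at 48.8 M, and W233fs/+ PK/PK replicate 1 the highest among PK/PK samples, at 68.1 M. Among TU/PK samples, nudt22 was highest in W233fs/+ replicate 1, at 5.94 CPM, and si:dkeyp-44a8.2 was highest in T428del/+ replicate 3, at 211 CPM. ENSDARG00000100547 was highest in T428del/+ replicate 3 among TU/PK samples, at 6.28 CPM, and in T428del/+ replicate 1 among PK/PK samples, at 0.326 CPM. si:ch211-203d1.3 was lowest among TU/PK samples in T428del/+ replicate 1, at 9.9 CPM, and highest among PK/PK samples in T428del/+ replicate 3, at 20.5 CPM. zgc:113364 had counts in a single TU/TU sample, W233fs/+ replicate 2, at 0.0583 CPM, which the rule flags by necessity. QPCT was highest among +/+ samples in TU/PK replicate 1, at 33.8 CPM, and acyp1 was highest among W233fs/+ samples in PK/PK replicate 1, at 33.3 CPM.

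The libraries T428del/+ TU/PK replicates 1 and 3 stood apart in scaling factor and mitochondrial share. Computed without mitochondrially encoded genes, the higher of their scaling factors was 0.927, still below the 0.96 to 1.05 of the other 25 libraries, which argues against those genes as the whole cause. Their deviations correlated with gene length at -0.157 in replicate 1, just outside the range of -0.134 to 0.184 of the other libraries, and at -0.0025 in replicate 3, so length bias stays open for the former and is argued against for the latter. In replicate 3, 10 of 10 marker lists of non-neuronal cells lay below the median library and both neuronal lists above it, so a lower share of non-neuronal cells may underlie it, whereas in replicate 1 only 5 of 10 did. The sources used here give no RNA quality, and an effect of their shared genotype was not tested. Replicate 2 of the same group lay at the other end, with the lowest mitochondrial share (11.9%) and the highest scaling factor (1.1) of the 27 libraries. On the second principal component replicate 1 lay at 102 and replicate 3 at -80.6.

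ENSDARG00000100547 and ENSDARG00000104112 were near absent in PK/PK and present in TU/PK. If reads had only moved to the other genes of their tandem cluster and been counted there, the summed level would have been kept. In PK/PK it was 28.8% of that in TU/TU, which argues against this. Reads that mapped to several genes were not counted, so the sum cannot tell whether PK reads were lost in that way. A silent or missing PK copy beside an unchanged TU copy would place TU/PK at 50% of the way, and without the libraries that stood apart the interval reached 23.3% for ENSDARG00000100547, which argues against it, and 53.7% for ENSDARG00000104112, for which it may hold. With all libraries the interval of ENSDARG00000104112 was -31.2% to 45.5%, which does not hold 50%. The outcome for that gene, of few counts, therefore depends on the libraries kept. A sequence difference that keeps PK reads from mapping, beside an unchanged TU copy, would also place TU/PK at 50%. The same intervals therefore argue against it as the whole cause for ENSDARG00000100547 and leave it open for ENSDARG00000104112. A higher output of the remaining TU copy was not tested, since gene counts do not tell alleles apart.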

How the results depend on the processing

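Leaving out both libraries that stood apart, leaving out psen1 and the bins of 100 kb were chosen after the result was seen, and the other alternatives were planned. Apart from the psen1 fold changes below, of 369 values of named genes under the alternatives that kept all libraries or left out both that stood apart, 349 kept their direction and their side of the threshold, 9 no longer passed, 11 came to pass and 0 changed direction. In the fits without a library, 889 of 918 did, 25 no longer passed (14 of them CLIC4 in T428del/+ and 10 FCF1), 4 came to pass and 0 changed direction. W233fs/+ against +/+ gave 2 genes in every refit of the model, at a false discovery rate of 0.01 and in all 27 fits without a library (1 when psen1 is not counted), and psen1 stayed lower, by -0.94 to -0.86. For the counts, odds ratios and fold changes below, the cause was not tested, except that fewer genes or samples enter under the stricter filter, the subsets and the thinned genes. Depth limits what can be seen for genes of few counts such as ENSDARG00000104112.

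DESeq2 called 19 genes for PK/PK against TU/TU, 1 for TU/PK against TU/TU, 20 for PK/PK against TU/PK, 15 for T428del/+, 28 for W233fs/+ against T428del/+, 425 for the interaction and 4 for the midpoint test. Within TU/TU, TU/PK and PK/PK it called 8, 1530 and 79 for T428del/+ and 12, 3 and 39 for W233fs/+, and for PK/PK within +/+, T428del/+ and W233fs/+ it called 26, 14 and 25. With limma-voom the counts were 16, 1, 40, 9 and 16 for the same main comparisons, 72 for the interaction and 5 for the midpoint test. It called 2, 1 and 346 for T428del/+ within TU/TU, TU/PK and PK/PK, 2 for W233fs/+ within TU/TU, and 7 and 5 for PK/PK within +/+ and W233fs/+. All of the genes called by edgeR were also called by DESeq2, with 9, 2, 4, 2 and 10 shared.

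With surrogate variables, 4 in number, the counts were 14 for PK/PK against TU/TU, 1 for TU/PK against TU/TU, 4 for PK/PK against TU/PK, 12 for T428del/+, 20 for W233fs/+ against T428del/+, 1 for the interaction and 4 for the midpoint test. For T428del/+ within TU/TU, TU/PK and PK/PK it was 1 each, for W233fs/+ within TU/TU and PK/PK 4 and 2, and for PK/PK within T428del/+ and W233fs/+ 2 and 8. Without both libraries that stood apart it was 15, 1, 17 and 12 for the first 4 of these comparisons and 4 for the midpoint test. T428del/+ within TU/PK and PK/PK then gave 0 and 291, W233fs/+ within TU/TU and PK/PK 1 and 45, and PK/PK within +/+ and T428del/+ 22 and 3.

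With only the samples compared, PK/PK against TU/TU gave 15. T428del/+ within TU/PK and PK/PK gave 0 and 92, W233fs/+ within TU/PK and PK/PK 3 and 7, and PK/PK within +/+ and T428del/+ 12 and 0. Size factors by median ratios gave 1 for T428del/+ within PK/PK. Library size alone gave 2 and 1 for T428del/+ within TU/PK and PK/PK, and 2 for PK/PK within T428del/+. No filter gave 3 and 1 for T428del/+ within TU/PK and PK/PK and 6 for W233fs/+ within PK/PK. The stricter filter gave 1 for PK/PK against TU/PK, too few to pass, with an odds ratio of 78.3 (adjusted p 0.924, Fisher's exact test), and 1 for the midpoint test. A false discovery rate of 0.01 gave 2 and 0 for T428del/+ within TU/PK and PK/PK and 0 for W233fs/+ within TU/PK.

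With the replicate number as a block, a pairing the data do not bear out, T428del/+ within TU/PK gave 613, and PK/PK within +/+ and T428del/+ gave 5 and 2. The main counts with this block were 10, 0, 2, 3, 2 and 11.

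With 1 gene per 100 kb the chromosome 14 odds ratio for PK/PK against TU/TU was 85.9 from a single called gene, which cannot pass (adjusted p 0.845, Fisher's exact test), with T428del/+ (123) and W233fs/+ against T428del/+ (223) still past 0.05. For PK/PK against TU/PK and W233fs/+ no called gene was left, so there was no odds ratio. With bins of 100 kb and without psen1 a single called bin was left, which cannot pass, with an odds ratio of 86.4 for PK/PK against TU/PK (adjusted p 0.841) and 72.4 for W233fs/+ (adjusted p 0.996, Fisher's exact test). Without psen1 alone, a single gene gave 75.1 for W233fs/+ (adjusted p 0.961), and near psen1 against the rest of chromosome 17 it was 21.5 (p 0.123, Fisher's exact test). Among the 200 smallest p, chromosome 17 in W233fs/+ fell to 3.39 with the thinned genes (adjusted p 0.145) and to 2.3 with surrogate variables (adjusted p 0.112, Fisher's exact test), and the other 5 comparisons passed under every alternative that kept all libraries. The psen1 fold change, not called in either comparison, changed sign for T428del/+ with limma-voom (0.00) and without both libraries that stood apart (-0.03), and for PK/PK with surrogate variables (-0.02). Camera with an estimated correlation and fry each called 0 gene lists for T428del/+, W233fs/+ and PK/PK.

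Without a library at a time, PK/PK against TU/TU gave 8 to 10 genes, TU/PK against TU/TU 0 to 1, PK/PK against TU/PK 2 to 5, T428del/+ 3 to 8, W233fs/+ against T428del/+ 9 to 13, the interaction 0 to 2600 and the midpoint test 2 to 3. T428del/+ gave 0 to 1, 0 to 4540 and 0 to 73 within TU/TU, TU/PK and PK/PK, with 4540 without T428del/+ TU/PK replicate 2 and 73 without replicate 3. W233fs/+ gave 0 to 1, 0 to 1 and 0 to 13, and PK/PK gave 1 to 9, 1 to 2 and 1 to 14 within +/+, T428del/+ and W233fs/+. The chromosome 14 odds ratio ran from 45.9 to 304 for PK/PK against TU/PK, and among the 200 smallest p from 2.38 to 4.34 for TU/PK against TU/TU. The psen1 fold change for PK/PK ran from -0.02 to 0.06. Lists called ran from 7 to 16 for T428del/+, 7 to 14 for W233fs/+ and 2 to 6 for PK/PK.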

Other observations

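The distance from psen1 and the regroupings of samples were planned. What the distance would have to show, leaving out psen1, the bins of 100 kb and the test of read mapping below were chosen after the result was seen.

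In the library T428del/+ TU/PK replicate 3, markers of endothelium stood 1.48 below the median library on the log2 scale, those of radial glia and astroglia 1.3 below and those of microglia 1.16 below, each the lowest of the 27. In replicate 1 of the same group, microglial markers stood 0.46 above the median, and those of glutamatergic and GABAergic neurons 0.36 and 0.33 below it. Skeletal muscle markers were highest in replicate 2 of that group, at 1.35 above the median. In T428del/+ against +/+ brains, clustered protocadherins had a median log2 fold change of -0.21 with 25 of 31 lower, and microglial markers one of 0.19 with 22 of 23 higher. Their adjusted p was 0.00016 and 0.0027 with the preset correlation, and adjusted p = 0.67 and 0.68 with an estimated correlation.

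Called genes lay on the chromosome whose genotype was compared. Variants linked to the selected genotype are a candidate explanation: they predict more called genes within 5 Mb of psen1 than beyond on chromosome 17, and with psen1 left out this held for T428del/+ (p = 0.00661) and W233fs/+ against T428del/+ (p = 0.000186), whereas W233fs/+ had a single such gene, too few to tell (p = 0.123, Fisher's exact test), though in the wider set at an unadjusted p under 0.05 its share was 17.5% within 5 Mb and 3.04% beyond (p = 2.97e-07, Fisher's exact test). Runs within 100 kb counted as separate genes are argued against as the whole cause for PK/PK against TU/TU, T428del/+ and W233fs/+ against T428del/+, where with bins of 100 kb in place of genes the chromosome compared still passed (adjusted p = 3.73e-11, 6.19e-05 and 5.73e-12, Fisher's exact test), but may hold for PK/PK against TU/PK, where both genes shared a bin, and a single bin cannot pass there (0.841) or for W233fs/+ (0.996). The bins do not join all neighbours: adam19b ends at 6614102 and si:dkeyp-44a8.2 starts at 6615564, and they fell in different bins. Longer runs were not tested, and the Fisher p-values here treat genes or bins as independent. Poorer mapping of PK reads would make called genes lower in PK/PK, but 3 of the 9 were higher. This argues against it as the whole cause. Beside an unchanged TU copy it would also place TU/PK midway between the homozygotes in CPM. For ENSDARG00000100547 the interval ended before midway with all libraries (at 21.3%) and without those that stood apart (23.3%). This argues against it as the whole cause there. The intervals of adam19b and si:dkeyp-44a8.2 missed midway only without those libraries (-12.3% to 46.7% and 75.9% to 99%). Poorer mapping stays open for the lower genes other than ENSDARG00000100547. An effect of psen1 on its neighbours cannot be separated from linkage on chromosome 17, and was not tested, since gene counts do not give the alleles of the linked genes.

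Random regroupings of the 27 samples within the other genotype, 100 per comparison with the real one included, tested whether chance could give as many called genes. A result as large came in 1 of 100 for PK/PK against TU/TU (9 genes, highest other 3), for T428del/+ (4, highest other 1), for W233fs/+ (2, highest other 0) and for W233fs/+ against T428del/+ (10, highest other 1). No other regrouping reached the real count there, which argues against chance. For PK/PK against TU/PK it came in 2 (2 genes, highest other 6), a share under 0.05. A regrouping exceeded the real count, so chance is not excluded for it. These shares are not adjusted over the comparisons. With a real count of 0 every regrouping is as large, so nothing can be said of chance for TU/PK against TU/TU (100 of 100, with 0 genes by edgeR, 458 at an unadjusted p under 0.05, and 1 each by DESeq2 and limma-voom; highest other 2). The same holds for the interaction (100 of 100, with 0 genes by edgeR, 2487 at an unadjusted p under 0.05 against 1038 by chance alone, 425 by DESeq2 and 72 by limma-voom, highest other 1) or the shared calls (100 of 100, with 0 by edgeR, 82 at an unadjusted p under 0.05 in both, highest other 0). For the TU/PK midpoint test 4 of 100 gave as many as the 2 genes, a share under 0.05, but some gave far more, so chance is not excluded for the count. Nothing is shown about the position of TU/PK either, since PK/PK at or near 0 puts these genes off the log midpoint. A regrouping with 650 genes points to a structure of the samples.

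For the chromosome compared among the 200 smallest p, no other regrouping held as many for PK/PK against TU/TU (90 genes, 1 of 100, highest other 21), PK/PK against TU/PK (38, 1 of 100, highest other 29), T428del/+ (49, 1 of 100, highest other 38) and W233fs/+ against T428del/+ (59, 1 of 100, highest other 27). This argues against chance for them, with shares not adjusted over the comparisons. For TU/PK against TU/TU 3 of 100 held as many as the 21, a share under 0.05, but a regrouping held 31. Its adjusted p also rose to 0.0594 without +/+ TU/PK replicate 1 (Fisher's exact test), so chance is not excluded. Nor can it be excluded for W233fs/+ (23, 5 of 100, highest other 31). For the gene lists called with a preset correlation chance cannot be excluded: 6 of 100 regroupings gave as many as the 16 of T428del/+ (highest other 19), 47 as many as the 10 of W233fs/+ (highest other 20) and 88 as many as the 5 of PK/PK (highest other 19).

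For 3 samples against 3 there are 10 splits, too few for a share under 0.05. For T428del/+ against +/+ the real count and the highest other were 6 and 711 within TU/PK (4 of 10 splits as large) and 4 and 0 within PK/PK (1 of 10), and the 711 genes point to a structure of the samples. For W233fs/+ they were 1 and 1 within TU/PK (2 of 10) and 1 and 0 within PK/PK (1 of 10). Within TU/TU the real count was 0 by edgeR, which all 10 splits reach by necessity, for T428del/+ (505 at an unadjusted p under 0.05, DESeq2 8, limma-voom 2; highest other 2) and for W233fs/+ (468 unadjusted, DESeq2 12, limma-voom 2; highest other 0). For PK/PK against TU/TU they were 3 and 0 within +/+, 1 and 0 within T428del/+, and 3 and 0 within W233fs/+ (1 of 10 for each).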
